A study of Mus musculus with 4 samples.

How the data were processed

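Single-cell RNA was measured in 4 libraries of cultured mouse muscle stem cells, 1 each for young cells on soft, young cells on stiff, aged cells on soft and aged cells on stiff substrate. Libraries were made with the droplet-based Chromium Single Cell 3' v3 chemistry, per the labels' protocols. Cell Ranger 6.1.2 and Partek are named, without their roles, per the submitters' processing notes. The genome build, the gene annotation and the filters on cells and genes were not given in the sources used here, so no coordinates are given. The deposited tables held log2(CPM + 1) per cell for 13772 genes, where CPM is UMIs scaled to a common total per cell over these genes. This unit was found from the values, whose sum is equal in all cells, to rounding, once the log2 is undone. A further deposited table paired gene symbols with Ensembl identifiers, and symbols are given as deposited, so that Ccn1 and Ccn2 appear as Cyr61 and Ctgf. Of 103 markers over the 12 classes, 26 were not found among the genes of the tables used here, among them Calcr of the myogenic progenitors.

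Because the tables held normalized values and not counts, the mean over cells of each cell's CPM was compared between libraries, as laid down before the data were examined for that case. The UMI counts could be worked back from the steps between values within a cell: between 99.987% and 99.991% of the values above 0 came out whole within 0.05. These counts served for depth, thinning, counting intervals and the alternative that sums counts over cells. For 9 symbols (Aldoa, Atp5o, Gcat, Ints5, Jakmip1, Nnt, Pick1, Sept2 and Zfp865) values fell between whole counts, and their levels are uncertain. Cells with at least 500 genes and at most 20% mitochondrial counts were kept. The median cell had 5570.5, 4990, 5111 and 5266 genes and 5.26%, 5.47%, 5.63% and 5.94% mitochondrial counts in young soft, young stiff, aged soft and aged stiff. Cells with under 1% mitochondrial counts numbered 21, 13, 83 and 109. Scrublet called 11 of 5910 cells doublets (0.186%), so few that the caller may not have worked, which was not checked. Doublets were not removed and remain in the values.

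The differences are log2 ratios of mean CPM plus a pseudocount of 5, over genes with at least 20 CPM in either library, and understate the difference of low genes. Each of the 4 comparisons (stiff against soft within each age, aged against young on each substrate) rests on 1 library per group, so no test, p-value or standard error was computed. Ratios of summed UMIs of named genes have the exact conditional binomial interval, and shares of cells the exact binomial one. Over named genes the interval's bounds lay a median of 4.90%, 5.25%, 5.47% and 4.96% and at most 11.3%, 12.8%, 19.7% and 21.3% from the ratio in the 4 comparisons. The genes named were, before the data were examined, set to be the 12 largest and 12 smallest log2 ratios of each comparison without unnamed gene models, the 8 largest and 8 smallest differences of the stiffness response between ages, up to 4 members with the largest absolute ratio of each fixed list, and Pax7, Myf5, Myod1, Myog, Spry1, Cdkn1a, Cdkn2a, Mki67, Cyr61, Ctgf, Ankrd1, Xrn1, Upf1, Dcp2 and Cnot1. Gm10076 and the genes of other cell types fall outside that rule and were chosen after their values were seen. The same holds for naming H2-D1 in the age comparison and for giving the values of some genes within clusters. A further gene that the rule names is not reported here and is also left out of the scatter plots and of the genes weighed for opposite responses, but it remains in the counts, correlations and scaling.

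The 28 gene lists were fixed before the data were examined: stem cell quiescence and self-renewal, myogenic commitment and fusion, sarcomere and contractile muscle genes, S phase, G2 and M phase, deadenylation, decapping and 5' to 3' decay, RNA exosome and 3' to 5' decay, nonsense-mediated decay, AU-rich element binding proteins, YAP and TAZ targets, actin cytoskeleton and SRF targets, fibrillar and basement membrane matrix, matrix proteases and inhibitors, integrins and focal adhesion, TGF-beta response, p53 and senescence, secreted inflammatory factors, interferon response, immediate early and dissociation response, glycolysis and hypoxia response, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, unfolded protein response, cholesterol synthesis, autophagy and lysosome, lipid and adipogenic genes, and sex-linked genes. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test.

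Cells of the 4 libraries were clustered together with the Leiden method at resolution 0.5 on 2000 variable genes, 30 principal components and 15 neighbours, with random seed 1. Clusters were named from markers of 12 cell classes fixed before the data were examined. Clusters 2, 3 and 5 were named myocyte-like, and clusters 0, 1 and 4 are given by number. A name needed at least 3 markers, so 3 of the 12 classes could not have been named: erythroid cells, with 0 of 5 markers found, adipocytes, with 1 of 5, and neutrophils, with 2 of 5. Of the endothelial markers 5 of 9 were found, and of the lymphocyte markers 3 of 7. Cluster 1 carried Pax7, Myf5, Cdh15 and Fgfr4 and cluster 0 Pax7, Myf5 and Fgfr4, but both also carried Ly6a, Col15a1 and Col3a1, which are fibroblast markers here. Clusters 0 and 1 together are called undifferentiated because they carried these progenitor markers and were not named myocyte-like, and Col15a1 and Col3a1 are also members of the matrix list. For shares of cells with a UMI and for cell cycle phase calls, each cell was thinned to 2000 UMIs. A phase is a range of a score, and 363, 414, 488 and 614 cells lay within 0.05 of the threshold.

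Matched transcript sequences came from GENCODE M21 on GRCm38, which may not be the build the authors used, and served only to count 30-base words of a gene's last 500 bases that also lie in transcripts of other genes. Tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9. The steps were tested on simulated data drawn from the real libraries. Of 67 genes set to differ 2-fold, 100% passed 1.5 times in each comparison, among 5957 genes for stiff against soft in young, 5361 for stiff against soft in aged, 5955 for age on soft and 5868 for age on stiff. Of 67 genes set to differ 1.5-fold, 31.3%, 25.4%, 26.9% and 19.4% passed, and of unaltered genes 0%. These draws held counting error only, on counts summed over cells. They had no variation between cells or libraries, so the 0% is no false-positive rate for the data. Of 60 simulated lists without a shift, for stiff against soft in young cells over 5989 genes, 6.67% fell outside the central 95% of random lists. Of lists with a fixed shift, larger than nearly all list medians for stiffness below, 100% did. Smaller shifts were not tried.

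Alternatives covered scaling, cell weighting, cell filters, doublet removal, pseudocount, expression floor, clustering and thinning. Of these 17 settings were planned before the data were examined and 4 were chosen after seeing the data: leaving out cells under 1% mitochondrial counts, only cells of 15000 to 50000 UMIs, clustering without the marker and list genes, and thinning to 20000 UMIs. With normalized values as the deposited unit, summed counts became the alternative to the mean over cells.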

Results

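Muscle stem cells of young and aged wild-type C57BL/6 mice were grown for 7 days on soft (12 kPa) or stiff (29 kPa) polydimethylsiloxane, an elastic silicone polymer, in medium with 10% fetal bovine serum, and were then profiled as single cells with droplet-based 3' RNA sequencing. The study asked how the stiffness of the substrate acts on aged muscle stem cells and whether RNA decay takes part. There were 4 libraries, 1 for each combination of age and stiffness, so that no difference below has a replicate check and no test or p-value is given. The tables held 1360 cells for young soft, 1481 for young stiff, 1333 for aged soft and 1739 for aged stiff, of which 1360, 1479, 1333 and 1738 passed the filters. The total UMI counts (molecules counted once each) were 50362148, 44005580, 47504701 and 68246016 in the same order, and the median cell held 35608, 28607, 33315 and 37067 UMIs. Levels are means over cells of CPM, the UMIs scaled to a common total per cell, and differences are log2 ratios of CPM plus 5. All intervals are 95% intervals and cover counting error only.

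Cells with the expression profile of differentiating myocytes made up a larger share of the aged libraries. These myocyte-like cells, named from contractile genes such as Acta1, Mylpf and Myl1, were 43.0% of young soft cells (exact binomial interval 40.4 to 45.7%), 45.8% of young stiff (43.3 to 48.4%), 65.2% of aged soft (62.6 to 67.8%) and 71.5% of aged stiff cells (69.3 to 73.6%). A cluster led by the proliferation genes Top2a and Mki67 (cluster 0) showed the opposite order, with 25.7% of young soft cells (23.4 to 28.1%), 22.7% of young stiff (20.5 to 24.9%), 7.50% of aged soft (6.15 to 9.05%) and 6.04% of aged stiff cells (4.97 to 7.27%). Cluster 1, in which the satellite cell genes Pax7 and Myf5 were highest, held 21.0%, 22.2%, 17.6% and 13.6% of the cells. Cluster 4, led by the cell cycle inhibitor Cdkn1c, held 10.3%, 9.33%, 9.68% and 8.86%. Cluster 4 also had the highest Myog of the 6 clusters (5408 CPM), so the myocyte-like share leaves out cells high in Myog. The myocyte-like class itself was split by age: cluster 2 held 31.3% of young soft and 33.6% of young stiff cells but 1.88% and 2.07% of the aged ones. Cluster 5 held 43.6% of aged soft and 52.4% of aged stiff cells but 1.40% and 2.37% of the young ones. Either may mark its libraries rather than a type. Of the cells with under 1% mitochondrial counts, cluster 5 held 76 of 83 in aged soft and 93 of 109 in aged stiff. When the cells were clustered without the marker genes and fixed lists, a setting chosen after seeing the data, the myocyte-like shares were 43.1%, 45.9%, 65.3% and 71.6%.

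**Figure D1:**
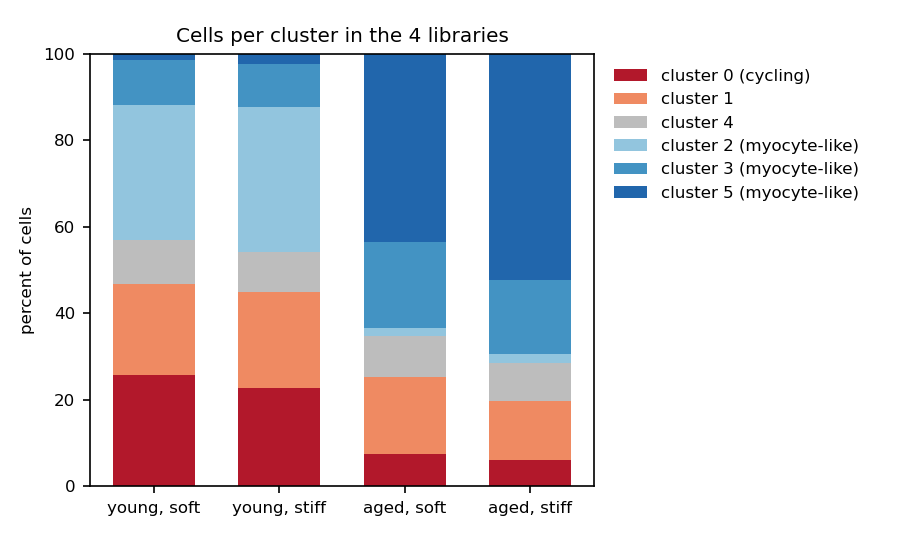
Stacked bars give the percent of passing cells in each of the 6 clusters, 1 bar per library. The myocyte-like clusters 2, 3 and 5 together take 43.0% and 45.8% of the young and 65.2% and 71.5% of the aged cells.

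Pax7 and Mki67 were found in fewer of the aged cells, and Myog and Cdkn1a in more of them. After every cell was thinned to 2000 UMIs, which left out 0 cells, a UMI of Pax7, the satellite cell transcription factor, was found in 12.4% of young soft cells (10.7 to 14.2%), 12.1% of young stiff (10.5 to 13.9%), 6.53% of aged soft (5.26 to 7.99%) and 6.67% of aged stiff cells (5.55 to 7.95%). In myocyte-like cells, which should lack Pax7, the thinned shares were 1.03%, 0.737%, 0.921% and 0.886%. Without thinning, Pax7 was found in 52.6%, 47.3%, 34.6% and 29.1% of all cells and in 15.7%, 10.3%, 15.9% and 13.3% of myocyte-like cells. The proliferation marker Mki67 was found in 13.3%, 13.0%, 4.35% and 3.45% of thinned cells and in at most 0.230% of myocyte-like cells. Myog, which drives differentiation, was found in 55.9%, 58.3%, 70.7% and 73.9%, and the cell cycle inhibitor Cdkn1a in 61.2%, 61.2%, 77.5% and 82.9%. For Myod1, the myoblast determination factor, the shares were 74.1%, 73.4%, 70.5% and 71.7%, and Myf5 was found in 17.3%, 12.2%, 11.0% and 9.67%. Spry1, an inhibitor of receptor tyrosine kinase signalling, was found in 4.78%, 4.73%, 4.43% and 4.72%. By score, 14.6%, 14.6%, 6.38% and 4.20% of thinned cells were called G2/M, against 0% to 0.242% of myocyte-like cells. Calls of S phase took 19.9%, 18.7%, 11.0% and 10.4% of thinned cells, but 6.15%, 9.29%, 9.90% and 7.57% of myocyte-like cells as well, so that the aged values lay near that background. Without thinning the S phase calls were 15.2%, 12.4%, 3.15% and 3.91%.

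The response of young cells to the stiffer substrate was small. Of 6034 genes measured at 20 CPM or more, 0 were at least 2 times higher on stiff and 2 were at least 2 times lower, among them Hist1h2ap. Sarcomere genes lay slightly higher and S phase genes slightly lower on stiff. The connective tissue growth factor gene Ctgf (Ccn2), a target of the mechanosensitive factors YAP and TAZ, stood at 24.4 CPM on soft and 11.8 CPM on stiff. Ankrd1, another such target, was higher on stiff (log2 ratio 0.21). It stood at 336 and 319 CPM within clusters 0 and 1 and at 1688 and 1970 CPM within myocyte-like cells. The YAP and TAZ target list had a median of -0.02 (percentile 66.6, inside the random range), with 8 members higher and 12 lower. Myf5 stood at 109 and 81.9 CPM.

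Among the genes lowest on stiff in young cells, the histone gene Hist1h2ap had 188 CPM on soft and 53.1 CPM on stiff (log2 ratio -1.73), Hist1h2ae 28.4 and 11.7 CPM, Hist1h4d 32.5 and 19.3 CPM, and Hist1h1b, a linker histone, 197 and 138 CPM. Gstp1, a glutathione transferase, had 91.4 and 46.6 CPM (-0.90). Usp50, of the ubiquitin protease family, had 90.8 and 59.98 CPM. Between 77.9% and 93.4% of the 30-base words in the last 500 bases of the Hist1h2ap, Gstp1 and Usp50 transcripts occur in transcripts of other genes, so these values are uncertain. The other histone genes named here were not searched for shared sequence, and their values are uncertain too. Igf2, the insulin-like growth factor, had 29.7 and 19.9 CPM, the splicing gene Snrpg 171 and 126 CPM, Erh 71.5 and 50.03 CPM, and the chromatin remodeller Hells 52.97 and 36.7 CPM. The genes highest on stiff included Prr9 (17.2 and 26.2 CPM, 0.49), the stretch-responsive muscle gene Ankrd2 (14.1 and 21.5 CPM, 0.47), the prolyl hydroxylase family gene P3h3 (17.7 and 24.99 CPM), and the small heat shock gene Hspb7 (90.9 and 122 CPM). Among them were also the calcium-binding Casq1 of the sarcoplasmic reticulum (233 and 304 CPM), Mustn1 (192 and 246 CPM) and Sypl2 (22.3 and 29.2 CPM). For the 24 leading genes and the others named here, the interval of a ratio of summed UMIs reached a median of 4.90% and at most 11.3% from the ratio. For Ctgf that ratio was 0.529 (exact conditional binomial interval 0.474 to 0.588).

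By gene list, 27 of 34 measured sarcomere and contractile genes were higher on stiff in young cells (median log2 ratio 0.09, above all of 10000 random lists of matched expression), with Tcap, a titin-binding Z-disc protein, at 301 and 355 CPM and the myosin light chain gene Myl1 at 6674 and 7740 CPM. Within myocyte-like cells, which took 43.0% and 45.8%, the sarcomere median was 0.02. Within clusters 0 and 1, which took 46.7% and 44.8%, the sarcomere median was -0.39. Some members were low there, such as Ckm (1.87 and 0.039 CPM). All 29 measured S phase genes were lower (-0.17, below all random lists), including the replication clamp Pcna at 50.9 and 40.0 CPM and the replicative helicase gene Mcm4 at 52.1 and 42.0 CPM, with a median of -0.16 within clusters 0 and 1. The median of the AU-rich element binding proteins, which control the stability of messenger RNAs, was -0.10 (percentile 0.67; -0.10 within clusters 0 and 1 and -0.05 within myocyte-like cells), with 15 of 18 members lower, such as Zfp36l1 at 55.3 and 48.8 CPM. Matrix genes had a median of -0.08 (percentile 0.69; -0.03 within clusters 0 and 1 and -0.02 within myocyte-like cells) and glycolysis genes 0.06 (percentile 99.8; 0.04 and 0.06). The other RNA decay lists lay within the range of random lists, with medians of -0.04 for deadenylation, -0.03 for decapping (0.02 with median-of-ratios scaling), -0.06 for the RNA exosome and -0.06 for nonsense-mediated decay. Xrn1, the 5' to 3' exonuclease, had 25.1 and 24.9 CPM, the nonsense-mediated decay helicase Upf1 44.4 and 43.9 CPM, the decapping enzyme Dcp2 20.5 and 17.9 CPM and the deadenylase scaffold Cnot1 41.8 and 41.3 CPM. No member of any list was at least 1.5 times higher or lower except Ctgf, which was lower.

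In aged cells, growth on the stiffer substrate went with higher sarcomere genes and lower G2 and M phase, matrix, and quiescence and self-renewal genes. Of 5552 genes measured, 2 were at least 2 times higher on stiff, among them Hist1h2ap, and 0 were at least 2 times lower. Hes1, a transcriptional effector of Notch signalling, stood at 107 CPM on soft and 62.5 CPM on stiff, and Ly6a, which encodes the surface antigen Sca-1, at 57.7 and 32.9 CPM. The share of myocyte-like cells was also higher on stiff, 71.5% against 65.2%, and cluster 1 took 13.6% against 17.6% of the cells.

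Hist1h2ap had 19.6 CPM on soft and 64.5 CPM on stiff in aged cells (log2 ratio 1.496), Gstp1 54.3 and 92.7 CPM (0.72), Usp50 82.8 and 139 CPM (0.71) and Bloc1s1, a lysosome-related organelle gene, 11.6 and 20.4 CPM (0.62). All are uncertain for the shared sequence named above, which covers Bloc1s1 too. Dqx1, a helicase-like gene, had 15.2 and 34.1 CPM (0.96), Ankrd2 30.1 and 44.9 CPM (0.51), the Z-disc gene Actn2 390.5 and 520 CPM (0.41), the slow myosin gene Myh7 62.6 and 83.2 CPM (0.38) and Sypl2 30.6 and 41.7 CPM. Below Hes1 (-0.73) and Ly6a (-0.73), the genes lowest on stiff were the fatty acid binding gene Fabp7 (47.0 and 27.7 CPM), the mitotic cyclin Ccnb1 (29.4 and 16.8 CPM), the spindle gene Hmmr (21.5 and 13.2 CPM), and Cdc20, an activator of the anaphase-promoting complex (27.4 and 17.3 CPM). Its ubiquitin-conjugating enzyme Ube2c had 54.7 and 37.1 CPM. Lower too were the water channel Aqp5 (30.7 and 19.5 CPM), Basp1 (29.7 and 19.0 CPM), Arl6ip1 (66.4 and 44.3 CPM) and Dpysl3 (76.2 and 52.9 CPM). The ratio of summed UMIs was 0.637 for Hes1 (interval 0.608 to 0.667) and 0.556 for Ly6a (0.521 to 0.594), and intervals of named genes reached a median of 5.25% from the ratio.

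Of the measured sarcomere genes, 34 of 35 were higher on stiff in aged cells (median 0.21, above all random lists), among them the perinatal myosin Myh8 (350 and 443 CPM) and the embryonic myosin Myh3 (1872 and 2358 CPM). Of the G2 and M phase genes, 23 of 25 were lower (-0.32, below all random lists), and Mki67 stood at 38.5 and 28.7 CPM. Within clusters 0 and 1 the sarcomere median was 0.29, and within myocyte-like cells 0.09. With the stiff library weighted to the shares of the 6 clusters in the soft one, the sarcomere median was 0.08. With weights for 3 classes (clusters 0 and 1, cluster 4 and myocyte-like cells), the G2 and M phase median was -0.04. The 11 measured S phase genes had a median of -0.04 (percentile 56.35), with 5 higher and 6 lower, and of 0.21 within clusters 0 and 1. Calls of S phase in those clusters took 14.6% of thinned cells on soft (11.02 to 18.9%) and 21.3% on stiff (17.1 to 26.1%), and calls of G2/M 23.6% and 19.9%. Without thinning the S phase calls there were 11.9% and 19.3%. Lower medians also held for matrix genes (-0.22, 18 of 21 lower), such as Col8a1 (72.9 and 52.99 CPM) and Bgn (347 and 275 CPM). Quiescence and self-renewal genes followed (-0.19, 15 of 16 lower), such as the Notch receptor Notch1 (24.6 and 17.5 CPM) and its effector Heyl (36.6 and 27.1 CPM). TGF-beta response genes (-0.19) included Id2 (153 and 125 CPM). All 3 medians lay below all random lists. Secreted inflammatory factors had a median of -0.21 over 6 genes, led by osteopontin, Spp1 (2208 and 1630 CPM), and the chemokine Ccl7 (26.6 and 18.6 CPM). Actin and SRF target genes (-0.15, 21 of 29 lower), with caldesmon, Cald1, at 244 and 178 CPM, and YAP and TAZ target genes (-0.14, 12 of 17 lower), with Igfbp3 at 89.8 and 69.3 CPM, lay at percentiles 0 and 0.02, and cholesterol synthesis genes (-0.13) at percentile 0.23. Within clusters 0 and 1 the medians lay nearer 0, at -0.02 for matrix, -0.07 for quiescence and self-renewal, -0.04 for TGF-beta response, -0.01 for secreted factors, -0.03 for actin and SRF target and -0.02 for YAP and TAZ target genes. Within myocyte-like cells they were -0.01, -0.10, -0.10, -0.04, -0.06 and -0.12. Some matrix genes were low there, such as Fn1 (4.91 and 7.47 CPM) and Col6a3 (0.97 and 1.23 CPM). The matrix median near 0 thus does not show that such genes were alike. Cholesterol synthesis genes stood at -0.05 within clusters 0 and 1 and at -0.07 within myocyte-like cells. The 5 measured interferon response genes had a median of -0.17 (percentile 1.41), or -0.11 within clusters 0 and 1 and -0.09 within myocyte-like cells. Glycolysis (0.10) and nuclear oxidative phosphorylation genes (0.05) were higher, with 0.01 and 0.02 within clusters 0 and 1 and 0.06 and 0.02 within myocyte-like cells.

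RNA decay genes in aged cells differed little between the substrates. The decapping list had a median of -0.09 with 14 of 15 members lower, at percentile 2.65 of the random lists and just inside their range. The decapping median was 0.02 within clusters 0 and 1 and -0.07 within myocyte-like cells. The deadenylation median was -0.02 (0.02 with median-of-ratios scaling), that of the exosome -0.06, of nonsense-mediated decay -0.07 and of AU-rich element binding proteins -0.08, all within the random range. Zfp36l2, which promotes decay of AU-rich messages, stood apart with 41.8 CPM on soft and 29.8 CPM on stiff. Xrn1 had 18.4 and 18.0 CPM, Upf1 39.3 and 38.8 CPM, Dcp2 14.9 and 12.9 CPM and Cnot1 29.8 and 30.8 CPM. Hes1 alone among list members was at least 1.5 times lower, and none was at least 1.5 times higher.

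Between the ages, the responses to stiffness shared part of their direction. Across 6212 genes the log2 ratio in young cells correlated with that in aged cells at Pearson's r 0.25 and Spearman's rho 0.40, a description across genes, which are not independent replicates, from 1 of 2 such correlations computed. The difference of the responses (aged minus young) was large and positive for Hist1h2ap (3.23), Gstp1 (1.62), Usp50 (1.27) and Bloc1s1 (1.12), which were lower on stiff in young and higher on stiff in aged cells. Other large positive differences were those of Hist1h2ae (1.08), Grcc10 (0.96) and Dqx1 (0.73). On the negative side stood Prr9 (-0.97), Ly6a (-0.95), P3h3 (-0.84), Hes1 (-0.75), Ccnb1 (-0.74), Tuba1c (-0.66), Arl6ip1 (-0.65) and Cdc20 (-0.64). None of these differences was tested, since each rests on 4 single libraries.

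**Figure D2:**
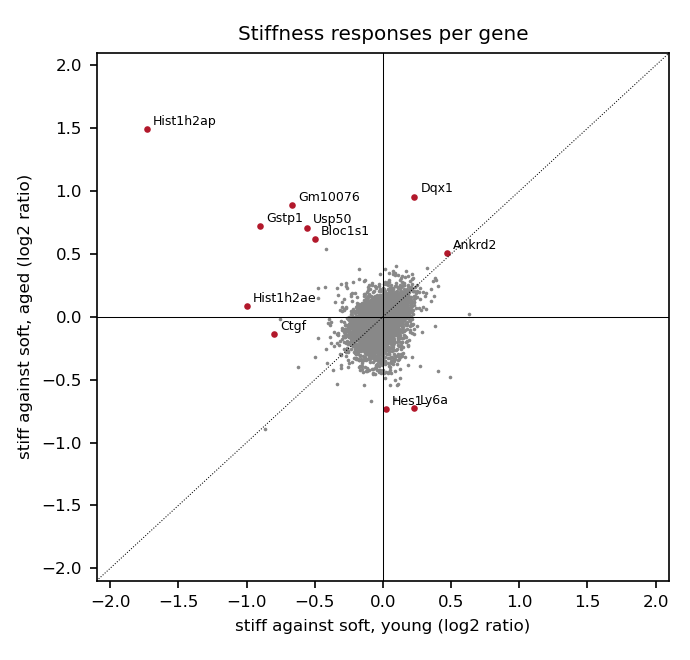
Each point is a gene with at least 20 CPM in any library; the axes give the log2 ratio of stiff against soft in young (horizontal) and aged cells (vertical), and the dotted line marks equal ratios. Most genes lie near 0 on both axes, while Hist1h2ap (-1.73 and 1.496) lies far from the line.

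On the soft substrate, aged cells had higher sarcomere and nuclear oxidative phosphorylation genes and lower cell cycle, matrix and unfolded protein response genes than young cells. Of 6147 genes measured, 45 were at least 2 times higher and 170 at least 2 times lower in aged cells. The antioxidant enzyme gene Gpx3 stood at 421 CPM in young and 1320 CPM in aged cells, muscle creatine kinase, Ckm, at 46.9 and 140 CPM, Pax7 at 72.7 and 41.8 CPM and Mki67 at 130.5 and 38.5 CPM. The all-gene median was -0.12, and scaling by median of ratios moved it to -0.01. Under that scaling 73 genes were at least 2 times higher and 118 at least 2 times lower. List medians of this comparison are read against that shift.

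The genes highest in aged cells on soft were R3hdml (3.3 and 29.2 CPM, log2 ratio 2.04), Ndrg4 (29.8 and 104 CPM, 1.65), Gpx3 (1.64), Ndrg2 (66.3 and 213 CPM, 1.61), and Ly6a (15.5 and 57.7 CPM, 1.61). Next came the glycoprotein-binding F-box gene Fbxo2 (5.0 and 23.6 CPM), the stress-responsive hormone gene Fgf21 (47.4 and 142 CPM, 1.48), Ckm (1.48), and Fam241a (17.9 and 56.6 CPM). The fast myosin Myh4 (7.3 and 28.0 CPM), Ccl7 (6.9 and 26.6 CPM) and the inositol synthesis enzyme Isyna1 (79.2 and 216 CPM) completed the 12 highest. Lowest were Hist1h2ap (188 and 19.6 CPM, -2.97, uncertain as above), Dmp1, an acidic matrix phosphoprotein (49.8 and 5.6 CPM, -2.37), Hist1h1b (197 and 37.7 CPM, -2.24) and carbonic anhydrase 3, Car3, of slow muscle (397 and 83.2 CPM, -2.19). They were followed by the PCNA-associated factor Pclaf (189 and 45.7 CPM), cyclin E2, Ccne2 (61.6 and 12.9 CPM), Hells (52.97 and 10.8 CPM), Atad2 (90.4 and 21.0 CPM) and the helicase subunit Mcm3 (74.7 and 17.1 CPM). Also low were the lipoprotein gene Apoe (197 and 51.1 CPM), Slfn9 (36.9 and 6.6 CPM) and the collagen VI chain Col6a3 (81.1 and 19.0 CPM, -1.84). The ratio of summed UMIs was 3.35 for Gpx3 (interval 3.30 to 3.41) and 0.183 for Car3 (0.177 to 0.190).

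All 29 measured S phase genes were lower in aged cells on soft, 26 of them by at least 1.5 times (median -1.21), and so were 38 of 43 G2 and M phase genes (-1.07), including topoisomerase Top2a (326 and 96.1 CPM) and the spindle factor Tpx2 (83.3 and 28.6 CPM). Within clusters 0 and 1, which held 46.7% of young soft and 25.1% of aged soft cells, the G2 and M phase median was -0.54 and the S phase median -0.90. Mki67 stood there at 278 and 151 CPM, and cluster 0 held 55.0% of these cells in young soft and 29.9% in aged soft. Matrix genes had a median of -0.86 with 18 of 26 at least 1.5 times lower, such as fibronectin, Fn1 (230 and 68.7 CPM), tenascin C, Tnc (40.4 and 8.9 CPM), and the collagen chaperone Serpinh1 (499 and 180 CPM), and of -0.31 within clusters 0 and 1. Unfolded protein response genes had a median of -0.56 with 10 of 21 at least 1.5 times lower, among them the endoplasmic reticulum chaperone Hsp90b1 (500 and 239 CPM) and the disulfide isomerases Pdia4 (103 and 48.7 CPM) and Pdia6 (263 and 143 CPM). Quiescence and self-renewal genes stood at -0.59 with 10 of 19 at least 1.5 times lower, such as Notch3 (62.0 and 26.5 CPM), syndecan 3, Sdc3 (101 and 36.0 CPM), and the collagen Col5a1 (34.7 and 11.4 CPM), and at -0.03 within clusters 0 and 1. TGF-beta response genes were lower in 14 of 14 cases (-0.52, and -0.20 within clusters 0 and 1), with the inhibitor Smad7 at 101 and 39.4 CPM and Tgfb1 at 88.4 and 43.5 CPM. Secreted inflammatory factors stood at -0.57 over 7 genes: Spp1 (5680 and 2208 CPM), Csf1, a macrophage growth factor (82.7 and 35.7 CPM), and 4 others were lower, while Ccl7 was higher. Their median was -0.21 within clusters 0 and 1 and 0.22 within myocyte-like cells. In myocyte-like cells matrix genes stood at -0.10, TGF-beta response genes at -0.24 and quiescence and self-renewal genes at -0.02. Some members were low there, such as Col6a3 (1.55 and 0.97 CPM) and Fn1 (7.65 and 4.91 CPM). Medians near 0 in these cells thus do not show that such genes were alike. Unfolded protein response genes had -0.43 in clusters 0 and 1 and -0.42 in myocyte-like cells.

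Sarcomere genes were higher in aged cells on soft, 15 of 35 by at least 1.5 times (median 0.51, above all random lists). Examples were the calcium pump Atp2a1 (448 and 1114 CPM) and Myh4, whereas Myh7 was lower (170 and 62.6 CPM). Within the myocyte-like cells, held mostly by cluster 2 in young and cluster 5 in aged libraries, the sarcomere median was -0.06, with 16 of 35 members higher. There Myh4 had 12.9 and 42.1 CPM (log2 ratio 1.39), Ckm 97.1 and 209 CPM (1.07) and Atp2a1 996 and 1659 CPM (0.73). Within clusters 0 and 1 the sarcomere median was -0.14. Nuclear genes of oxidative phosphorylation were higher in 60 of 63 cases (0.29), though none reached 1.5 times, with the ATP synthase subunit Atp5e at 1225 and 1727 CPM. Their median was 0.05 within clusters 0 and 1 and 0.19 within myocyte-like cells. Commitment and fusion genes had a median of 0.32, of 0.16 within clusters 0 and 1 and of -0.05 within myocyte-like cells, with the fusion factors Mymx (54.9 and 145 CPM) and Mymk (972 and 1577 CPM) and brain creatine kinase, Ckb (199 and 377 CPM), while Myog had 1533 and 1910 CPM and Myod1 897 and 923 CPM. Only 5 of 34 interferon response genes in the table were measured: the class I antigen genes H2-K1 (31.2 and 62.3 CPM) and H2-D1, Bst2 (11.7 and 25.7 CPM) and Ifi27 (111 and 205 CPM) were higher and B2m was lower (88.9 and 64.1 CPM), with a median of 0.85 (0.70 within clusters 0 and 1, 0.77 within myocyte-like cells). The p53 and senescence list stood at 0.14 (percentile 98.5), at 0.28 within clusters 0 and 1 and at -0.13 within myocyte-like cells, with Cdkn1a at 1244 and 1622 CPM, Cdkn2a, which encodes p16 and p19Arf, at 28.9 and 24.9 CPM, and the nuclear lamina gene Lmnb1 at 57.0 and 22.7 CPM.

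Actin and SRF target genes had a median of -0.29 (percentile 0.08; -0.03 within clusters 0 and 1) but went both ways, with 10 of 31 at least 1.5 times lower, such as Tpm4 (282 and 111 CPM) and Actg1 (1157 and 573 CPM), and 6 at least 1.5 times higher, such as Tpm3 (349 and 747 CPM). YAP and TAZ targets had a median of -0.28 (percentile 5.47, inside the random range), with Ctgf (24.4 and 10.1 CPM) and Cyr61 (Ccn1; 98.7 and 57.6 CPM) lower and Ankrd1, also a muscle stress gene, higher (934 and 1774 CPM). Glycolysis genes stood at -0.26 (percentile 0.77), with muscle phosphofructokinase, Pfkm, higher (124 and 219 CPM) and the liver isoform Pfkl lower (45.5 and 25.6 CPM). The remaining lists lay inside the random range: integrins and focal adhesion -0.23, lipid and adipogenic genes -0.27, immediate early genes -0.23, matrix proteases and inhibitors -0.17, autophagy and lysosome -0.07 (0.04 with median-of-ratios scaling), mitochondrially encoded genes -0.02 (0.10), cholesterol synthesis -0.00 (0.10), and sex-linked genes 0.30 over Ddx3y and Eif2s3y. Single members differed, such as the autophagosome gene Map1lc3a (385 and 954 CPM) and the matrix protease inhibitor Timp1 (322 and 107 CPM). Within clusters 0 and 1 and within myocyte-like cells, YAP and TAZ targets had medians of -0.04 and -0.19, glycolysis genes -0.28 and -0.33, cholesterol synthesis genes 0.14 and 0.30, lipid and adipogenic genes 0.13 and 0.03, matrix proteases and inhibitors -0.14 and 0.18, and mitochondrially encoded genes 0.09 and -0.24.

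RNA decay genes were mostly lower in aged cells on soft, with medians inside the range of random lists of the same expression. The medians were -0.22 for deadenylation (percentile 13.2), -0.16 for decapping (42.9), -0.26 for the exosome (11.8), -0.24 for nonsense-mediated decay (10.2) and -0.26 for AU-rich element binding proteins (6.07). Within clusters 0 and 1 they were -0.11, -0.05, -0.19, -0.15 and -0.11 in the same order. Within myocyte-like cells they were -0.20, -0.02, -0.06, -0.13 and -0.16. Pabpc1, the cytoplasmic poly(A) binding protein, stood at 474 and 249 CPM, the deadenylase Cnot6 at 57.2 and 31.1 CPM, Zfp36l2 at 80.8 and 41.8 CPM, the exosome subunits Exosc8 at 46.9 and 25.2 CPM and Dis3 at 24.4 and 14.1 CPM, and Lsm2, of the ring that aids decapping, at 90.3 and 54.2 CPM. Xrn1 had 25.1 and 18.4 CPM, Cnot1 41.8 and 29.8 CPM, Dcp2 20.5 and 14.9 CPM and Upf1 44.4 and 39.3 CPM.

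On the stiff substrate, aged and young cells differed in largely the same genes as on soft. Of 6047 genes measured, 54 were at least 2 times higher and 229 at least 2 times lower in aged cells, and 35 of the higher and 143 of the lower genes passed 2 times on both substrates. Across 6212 genes the age ratios on soft and stiff correlated at r 0.94 and rho 0.95. Pax7 stood at 66.2 CPM in young and 32.0 CPM in aged cells, Mki67 at 128 and 28.7 CPM, Top2a at 328 and 74.4 CPM and Fgf21 at 39.6 and 161 CPM. The all-gene median was -0.13, or -0.00 with median-of-ratios scaling, under which 85 genes were at least 2 times higher and 177 at least 2 times lower.

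Among the genes highest in aged cells on stiff were Fgf21 (log2 ratio 1.89), Ckm (51.0 and 177 CPM, 1.70), Ndrg2 (69.7 and 223 CPM, 1.61), R3hdml (5.8 and 27.4 CPM), and Atp2a1 (459 and 1351 CPM, 1.55). They were joined by Ndrg4 (31.4 and 99.1 CPM), Scd1, a fatty acid desaturase (38.3 and 118 CPM, 1.51), Fam241a (17.8 and 58.5 CPM), Myh4 (7.2 and 27.9 CPM), Gpx3 (484 and 1292 CPM, 1.41) and the semaphorin Sema4d (13.7 and 43.3 CPM). Lowest were Dmp1 (42.8 and 4.5 CPM, -2.32), Col6a3 (89.4 and 14.6 CPM, -2.27), Prr9 (26.2 and 2.1 CPM, -2.14), Top2a (-2.07), Hist1h1b (138 and 29.2 CPM, -2.06), and Mki67 (-1.98). Next were placental growth factor, Pgf (101 and 23.8 CPM), Pclaf (165 and 41.4 CPM), Hmmr (61.5 and 13.2 CPM), Fn1 (217 and 56.0 CPM, -1.86), Timp1 (361 and 96.0 CPM, -1.86) and Car3 (362 and 103 CPM, -1.77). The ratio of summed UMIs was 4.19 for Fgf21 (interval 3.999 to 4.401) and 0.131 for Col6a3 (0.121 to 0.142).

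S phase genes had a median of -0.997 with 22 of 26 at least 1.5 times lower, G2 and M phase genes -1.33 with 36 of 41, and matrix genes -0.87 with 20 of 26. Quiescence and self-renewal genes had a median of -0.69 with 10 of 18, secreted inflammatory factors -0.65 over 5 genes, unfolded protein response genes -0.56 with 10 of 21 and TGF-beta response genes -0.53 with 7 of 14. Within clusters 0 and 1 the medians were -0.52 for S phase, -0.61 for G2 and M phase, -0.31 for matrix, -0.06 for quiescence and self-renewal, -0.24 for secreted factors, -0.47 for unfolded protein response and -0.20 for TGF-beta response genes. Within myocyte-like cells matrix genes stood at 0.01, secreted factors at 0.32, unfolded protein response genes at -0.37 and TGF-beta response genes at -0.31. Some matrix genes were low there, such as Fn1 (7.57 and 7.47 CPM) and Col6a3 (1.49 and 1.23 CPM). A matrix median near 0 thus does not show that such genes were alike. Hes1 stood at 175 and 62.5 CPM, Tgfb2 at 380 and 179 CPM, Calr, a calcium-binding chaperone, at 450 and 234 CPM, and Csf1 at 79.8 and 29.3 CPM. Actin and SRF target genes had a median of -0.37 (-0.09 within clusters 0 and 1) with 11 of 31 at least 1.5 times lower, among them the beta-actin gene Actb (2723 and 1139 CPM) and Tagln2 (265 and 77.1 CPM), and YAP and TAZ targets of -0.30 (percentile 3.81), with Cyr61 at 99.7 and 52.5 CPM and Ankrd1 at 1080 and 1880 CPM. Ankrd1 had 319 and 266 CPM within clusters 0 and 1 and 1970 and 2494 CPM within myocyte-like cells. Sarcomere genes (0.58, 17 of 35 at least 1.5 times higher), such as the fast troponin Tnni2 (379 and 918 CPM), oxidative phosphorylation genes (0.30, 59 of 63 higher), commitment genes (0.25) and the 5 interferon response genes (0.45) were higher. Within myocyte-like cells these medians were 0.08 for sarcomere, 0.16 for oxidative phosphorylation, -0.10 for commitment and 0.83 for interferon response genes. Within clusters 0 and 1 these medians were 0.39, 0.08, 0.20 and 0.63 in the same order. The p53 and senescence list stood at 0.05 (percentile 90.3), at 0.28 within clusters 0 and 1 and at -0.12 within myocyte-like cells. RNA decay lists again lay within the random range, at -0.21 for deadenylation, -0.19 for decapping, -0.25 for the exosome, -0.25 for nonsense-mediated decay and -0.22 for AU-rich element binding proteins. In the same order they stood at -0.07, -0.05, -0.12, -0.10 and -0.08 within clusters 0 and 1. Within myocyte-like cells they stood at -0.17, 0.02, -0.03, -0.13 and -0.13. Zfp36l2 (71.4 and 29.8 CPM), Pabpc1 (456 and 234 CPM) and Exosc2 (100.3 and 54.3 CPM) had the lowest ratios of the AU-rich, deadenylation and exosome lists, and Xrn1 had 24.9 and 18.0 CPM.

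**Figure D3:**
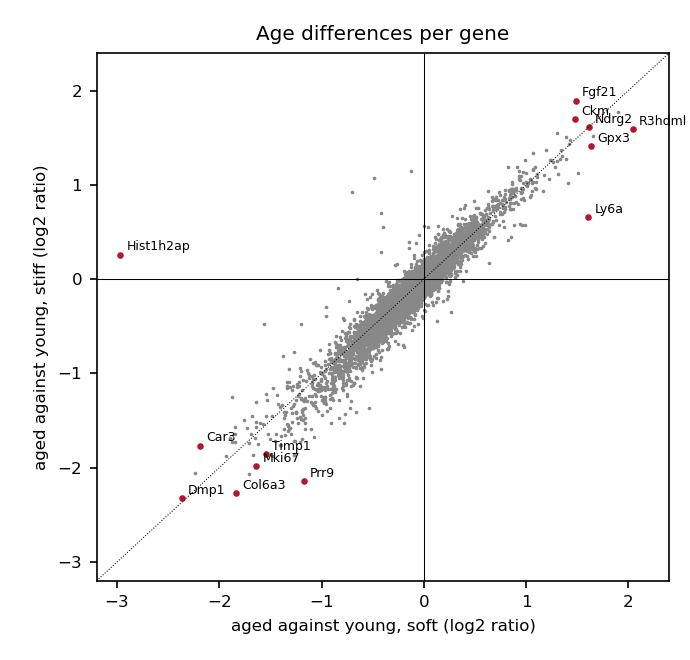
Each point is a gene with at least 20 CPM in any library; the axes give the log2 ratio of aged against young on soft (horizontal) and on stiff substrate (vertical), and the dotted line marks equal ratios. Most genes lie along the line (r 0.94), with Hist1h2ap far from it.

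**Figure D4:**
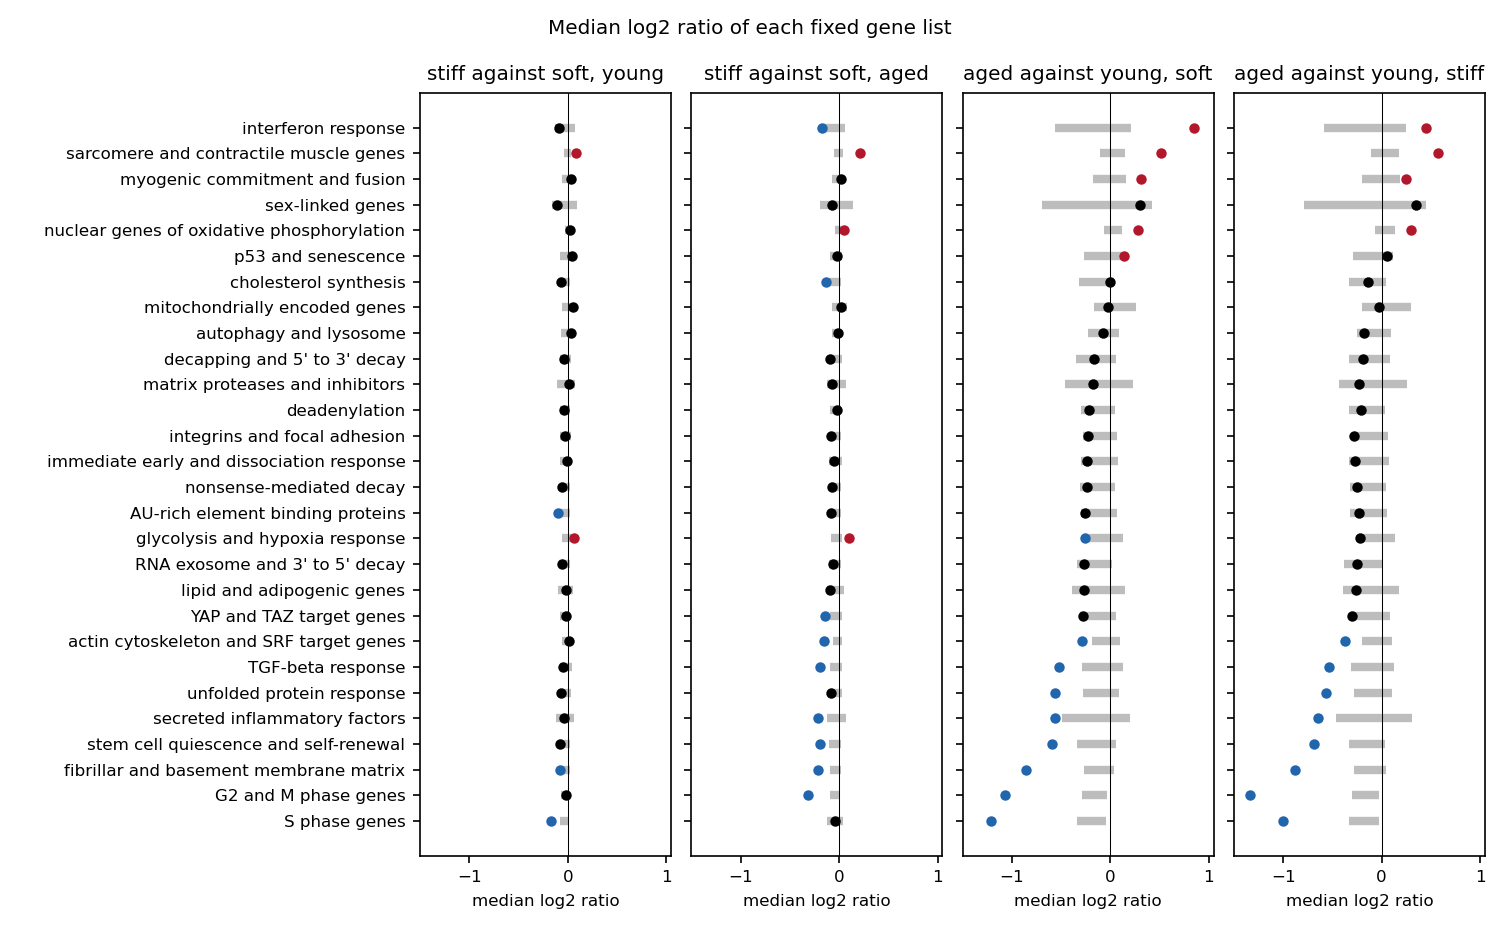
Points give the median log2 ratio of the measured members of each of the 28 fixed gene lists in the 4 comparisons, and grey bars the central 95% of 10000 random lists of matched expression. Red points lie above and blue points below that range, and black points lie inside it; with age the S phase (-1.21 on soft) and G2 and M phase lists (-1.33 on stiff) lie farthest below 0.

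Transcripts of other cell types differed between the libraries in both directions. A UMI of Lyz2, the lysozyme of macrophages, occurred in 11 young soft, 8 young stiff, 206 aged soft and 295 aged stiff cells without thinning, with at most 3 UMIs in any cell and exactly 1 UMI in 186 of the 206 and 260 of the 295 cells. UMIs of the complement gene C1qb occurred in 0, 1, 27 and 31 cells. In thinned cells Lyz2 was found in 0, 1, 18 and 18 cells. The B cell receptor gene Cd79a was found in 35, 45, 157 and 225 cells without thinning, and the fibroblast gene Dpt in 46, 37, 3 and 10. Other fibroblast markers went different ways, with Col15a1 in 244, 232, 20 and 27 cells, Dcn in 28, 31, 27 and 35, Pdgfra in 28, 19, 25 and 29 and Ly6a in 219, 240, 241 and 253. The T cell receptor gene Trbc2 was found in 37, 46, 13 and 10 cells and the macrophage gene Cd68 in 39, 53, 47 and 59.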

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

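The tests of cell shares as the whole cause were chosen only after the results had been seen, as were the 95% spread over redrawn cells and the requirements that a bound be passed by more than that spread and that a median near 0 not rest on members that go both ways, while the bounds of the other tests were written beforehand.

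Named for opposite directions of the stiffness response in young and aged cells were 3 genes, a difference between the ages that was not tested because each group is 1 library. The aged response minus the young one was 3.23 on the log2 scale for Hist1h2ap, 1.62 for Gstp1 and 1.55 for Gm10076, whose mean level was 837, 526, 596 and 1108 CPM in young soft, young stiff, aged soft and aged stiff.

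For these genes with Usp50 and Bloc1s1, different shares of the cell clusters were argued against: the smallest median difference in any of the 6 clusters was 1.09 against 1.55 over all cells, a ratio of 0.700 (0.537 to 0.845 over redrawn cells). Redrawing the 5 genes instead gave 0.0628 to 0.955, which reaches below the bound of 0.5, and the spread over cells was preferred after both had been seen. Reads shared with near-identical copies remain a candidate explanation, since 100% of the 5 genes have such a copy against 3.2% of 250 genes of matched expression. That result shows that reads could be split between copies, and not that the split differed between libraries. For Gstp1, Gm10076, Usp50 and Bloc1s1, levels fell from aged stiff to young soft, aged soft and young stiff. The median UMIs per cell have the same order (37067, 35608, 33315 and 28607), but the levels of Hist1h2ap do not. These genes were selected for being lower on stiff in young and higher on stiff in aged cells. That selection fixes part of the order, so its match with depth carries little weight. Whether depth took part was not weighed. A biological difference between young and aged cells stays open and untested.

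In aged cells on soft, shares of cells and a difference within cells cannot be told apart for the higher sarcomere genes, because members went both ways within the myocyte-like cells: the median was -0.059 there against 0.51 over all cells (ratio -0.115, -0.219 to 0.00819) and lay 0.0092 from that of all measured genes (-0.043 to 0.072), but 16 of 35 members were higher, with Myh4 at 1.39 and Ckm at 1.07. That class was itself named from contractile genes, which can pull the median towards 0, and cluster 2 holds most of it in young and cluster 5 in aged libraries. The sarcomere ratio and its spread alone would meet the bound written for an effect of the shares. The requirement on members, applied only later, keeps this open. In these libraries, a lower share of undifferentiated cells was argued against as the whole cause of the lower matrix and G2 and M phase genes. Within clusters 0 and 1, which carry fibroblast as well as progenitor markers, the matrix median lay -0.27 from that of all measured genes (-0.39 to -0.16). The G2 and M phase median lay -0.50 from it (-0.78 to -0.25). These spreads cover redrawn cells and not variation between libraries. Cluster 0, led by cycle genes, held 29.9% of these cells (24.999 to 35.1, counting error only) against 55.0% (50.997 to 58.9) in young soft. The G2 and M phase difference there may thus itself come from the share of cluster 0. No list median within cluster 0 alone was computed. Over all libraries, Mki67 had 512 CPM in cluster 0 and 9.29 CPM in cluster 1, and Top2a 1306 and 11.3 CPM. Within clusters 0 and 1 together, Mki67 had 278 CPM in young soft and 151 CPM in aged soft, and Top2a 693 and 376 CPM. The G2 and M phase values therefore do not separate a difference within cells from the share of cluster 0. Whether a lower share of undifferentiated cells accounts for most of the difference stays open. Within clusters 0 and 1 the medians were -0.31 against -0.86 for matrix (ratio 0.364, 0.237 to 0.536). For G2 and M phase genes they were -0.54 against -1.07 (ratio 0.506, 0.267 to 0.830). The ratio of 0.506 alone would just meet the bound written against an effect of the shares, but its spread, applied only later, does not. Shares and a difference within cells cannot be told apart as the larger part because both spreads cross both bounds. Age itself stays open as an explanation for all 3 lists, and with 1 library per group it is confounded with the library.

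In aged cells the myocyte-like share was also higher on stiff than on soft, and different cluster shares may account for part of the higher sarcomere and lower G2 and M phase genes. With the stiff library weighted to the soft library's shares of the 6 clusters, the sarcomere median was 0.075 against 0.21 (ratio 0.358, 0.135 to 0.535). It lay 0.088 (0.026 to 0.16) above that of all measured genes. In these libraries, that argues against the shares of these 6 clusters as the whole cause. The spread covers redrawn cells only, and the weights leave shifts among cells inside a cluster in place, so finer shares stay open. How much the cluster shares account for also stays open, because the spread of the ratio crosses the lower bound. Weighted by 3 classes (clusters 0 and 1, cluster 4 and myocyte-like cells), the G2 and M phase median was -0.036 against -0.32 and lay -0.022 from that of all measured genes (-0.30 to 0.14). Its ratio of 0.113 alone would meet the bound written for an effect of the shares, but the spread of -2.19 to 0.611, applied only later, keeps this open too. An effect of stiffness within aged cells stays open and untested.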

How the results depend on the processing

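The settings that leave out cells under 1% mitochondrial counts, keep only cells of 15000 to 50000 UMIs, cluster without marker and list genes or thin to 20000 UMIs were chosen after seeing the data. Of 551 values of named genes, 202 passed 1.5 times. All 202 kept their direction under the 12 alternatives run for them, while 169 passed 1.5 times under each. The floors of 5 and 50 CPM do not enter these values, and a pseudocount of 1 or 20 cannot reverse a direction. Those settings were therefore no check of direction. The fewest still past it were 173 with a pseudocount of 20, which by construction shrinks low genes, and 190 with median-of-ratios scaling. Lists with a median past 0.2 kept their direction in 4 of 4 cases for stiffness in aged cells, 21 of 22 for age on soft and 22 of 23 for age on stiff; the exception was the sex-linked list, at -0.02 on soft and -0.10 on stiff with a floor of 5 CPM. The planned run on myogenic-like clusters alone was not made, since no cluster was named as another type (3 of the 12 classes lacked the markers for it). No paired analysis of replicates was possible because each group had 1 library, and a fit of age with both substrates as pairs was not run. Outside the main interval lay 111 of 140 alternative regulator shares, 16 of 40 phase shares and 10 of 64 cluster shares. The regulator and phase shares among these came from thinning to another number of UMIs or none, which changes depth by construction. By their own limits, 117 of 1340 list medians and 1138 of 6804 named gene values moved.

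For genes at least 2 times lower on stiff, a pseudocount of 1 gave 4 in young and 1 in aged cells, and summed counts gave 1 in aged cells. For age on soft, genes at least 2 times higher numbered 73 with median-of-ratios scaling, 69 with a pseudocount of 1 and 23 with a pseudocount of 20, and genes at least 2 times lower 61 with a pseudocount of 20 and 92 with a floor of 50 CPM. On stiff, the higher genes numbered 85 with median-of-ratios scaling and 23 with a pseudocount of 20, and the lower ones 93 with a pseudocount of 20 and 129 with a floor of 50 CPM, where fewer genes are counted by construction. Pearson's r of the stiffness ratios across ages was 0.179 with a floor of 50 CPM and 0.317 with cells of 15000 to 50000 UMIs. In the main setting it was 0.25. Spearman's rho was 0.43 and 0.46 in these settings, against 0.40 in the main one. The cause was not tested.

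The myocyte-like share at resolution 1.0 was 46.5% in young soft, 68.7% in aged soft and 74.7% in aged stiff, and with another random seed 40.3% in young soft, 41.7% in young stiff and 62.0% in aged soft. It was 67.9% in aged soft with at least 1000 genes and at most 10% mitochondrial counts, and, without cells under 1% mitochondrial counts, 46.3% in young soft, 48.5% in young stiff and 73.7% in aged stiff. The cause was not tested. S phase calls took 24.3% of young soft, 16.7% of aged soft and 17.3% of aged stiff cells at 1000 UMIs, 15.2% of young stiff and 6.83% of aged soft at 5000 UMIs, 16.7%, 12.9%, 2.80% and 4.04% of the 1259, 1213, 1180 and 1608 cells deep enough for 20000 UMIs (101, 266, 153 and 130 shallower ones left out), and 15.2%, 12.4%, 3.15% and 3.91% without thinning. G2/M calls at 1000 UMIs took 17.2% of young stiff, 10.4% of aged soft and 7.25% of aged stiff cells. Thinning itself adds S phase calls: in myocyte-like cells they were 6.15%, 9.29%, 9.90% and 7.57% at 2000 UMIs and 0.171%, 0.442%, 0.115% and 0% without thinning.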

Other observations

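The values within clusters given here were chosen after the values over all cells had been seen, and no test was run on them. Within clusters 0 and 1, Pax7 stood at 148, 142, 149 and 144 CPM in young soft, young stiff, aged soft and aged stiff, close to level, while over all cells it was lower in aged libraries. The quiescence and self-renewal list likewise had an age median of -0.03 on soft and -0.06 on stiff within these clusters. Other genes differed between ages within these clusters or within myocyte-like cells, of which cluster 2 holds most in young and cluster 5 most in aged libraries, so the latter are not the same cells. Gpx3 stood at 549, 627, 1946 and 1895 CPM in clusters 0 and 1 and at 315, 373, 1163 and 1185 CPM in myocyte-like cells, and Ndrg2 at 79.5, 84.8, 257 and 259 CPM in myocyte-like cells. Cdkn1a, at 194, 205, 366 and 362 CPM in clusters 0 and 1, was higher in the aged libraries there, and in myocyte-like cells lower, at 2286, 2364, 2009 and 1910 CPM. Ly6a had 32.4, 41.7, 223 and 157 CPM in clusters 0 and 1.

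Car3 had 850, 731, 118 and 134 CPM in myocyte-like cells. The endoplasmic reticulum chaperone Hspa5 was lower in aged libraries in both kinds of cells, at 489, 521, 306 and 332 CPM in clusters 0 and 1 and 356, 354, 231 and 242 CPM in myocyte-like cells. The unfolded protein response list had age medians of -0.43 on soft and -0.47 on stiff in clusters 0 and 1 and of -0.42 and -0.37 in myocyte-like cells. Hes1, lower on stiff in aged cells, stood at 327 and 209 CPM on soft and stiff within clusters 0 and 1 of the aged libraries and at 335 and 350 CPM in those of the young ones.

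Scx, a tendon transcription factor gene, stood at 139, 162, 292 and 301 CPM over all cells of the 4 libraries in the same order. The other tendon markers did not share this: Fmod had 3.80, 5.44, 1.08 and 1.08 CPM, Comp 0.766, 0.924, 0.326 and 0.265 CPM, and Mkx 2.19, 1.56, 2.29 and 1.84 CPM, Thbs4 had at most 0.242 CPM and Tnmd at most 0.0617 CPM.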
